A study of Drosophila melanogaster with 6 samples.

How the data were processed

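RNA bound by Orb, a cytoplasmic polyadenylation element binding protein of the Drosophila germline, was compared with RNA from a mock immunoprecipitation (IP) made with mouse IgGs, using ovaries of females aged 3 to 5 days. Each of the 6 arrays carried both RNAs of a replicate, and per the labels Orb IP RNA was in Cy3 on 3 arrays and in Cy5 on the other 3. Per the labels' protocols, RNA was amplified and labelled by an amino allyl method. The labels do not say whether replicates were separate ovary preparations, so p-values measure only the spread between these arrays, which may be technical.

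Per the file headers, the arrays were quantified with ArrayVision, and the deposited intensity of a spot is its volume (grey levels times area) in each dye with a local background. The deposited subtracted intensity equals volume minus background, set to 0 where background was higher. The other deposited columns hold the log10 of the subtracted volume and a normalized log10 ratio of Cy3 over Cy5, in which Cy5 had been brought to the scale of Cy3 by a method not given in the sources used here. Each array held 15744 spots in 24 blocks of 656. Spots carry a block, row and column, and the files do not pair them with probe or gene names. The 17 gene lists, the 8 lists of cell type markers and the rule for named genes, all fixed before the data were examined, were therefore not analysed here.

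A spot counted as above background in a channel when its volume minus background exceeded the channel's median by 2 robust SDs, estimated from the lower part of the distribution. This limit was chosen after seeing the data, because the planned limit needed a background SD or labelled control spots. In row 1, columns 3 to 12 of all 24 blocks, 240 spots were above background in both dyes on all 6 arrays. They were treated as control positions, from their position and values alone, and left out of the tests. Software marks on 5 spot values of 2 arrays were left out as well.

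The fit fixed before the data were examined used normexp background correction with offset 50, loess within each array (span 0.3, control positions at weight 0), and limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a dye term. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 over the 1432 spots above background in either channel on at least 3 arrays. Median centring of each array's log ratios, listed as another normalization before the data were examined, is reported beside it, a choice made after seeing the data. The median was taken over the 15504 spots outside the control positions, of which 12269 were above background in neither channel on any array. It therefore rests mostly on spots without detected signal, and does not measure a difference between the dyes at spots with signal. Log2 ratios carry the offset, so they understate the ratio of dim spots. Lower bounds on the ratio divide the Orb IP volume by the higher of the mock IP volume and the mock IP detection limit on each array, without normalization between dyes, and are averaged over arrays on the log2 scale unless stated. They take a spot without RNA to read 0 after background subtraction, and can be too high where the mock IP channel's median was below 0.

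Both fits were tested on simulated arrays with the noise of the real channels. In the first simulation, a set of spots with signal in both channels was raised in the Orb IP channel. Other spots outside the control positions had no signal, and 220 spots were tested. The raised spots were brighter than most real ones, whose mock IP signal was mostly near background. The recoveries may therefore not hold for dim spots. Loess recovered 0% of spots changed 2-fold, 17.9% of those changed 4-fold and 77.3% of those changed 16-fold, and called 59, 34 and 3 of them in the opposite direction. Median centring recovered 100% at each size. Only the raised spots had signal, so at their intensities loess could fit little else, and the median lay at spots without signal. This set-up favoured median centring in advance. Neither simulation held a difference in gain between the dyes, so they cannot show which fit is right on the real arrays. With changes in both directions among many unchanged expressed spots, 3200 were tested, and both methods recovered 98.5% of 2-fold changes.

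The naming rule ranks genes, and here its ranking was applied to spots after median centring. The 2 highest spots are given. No lower spot met the rule, so the 2 called lower are given, chosen after their values were seen. Alternatives covered background correction, normalization within and between arrays, filters, the dye term, array weights, single orientations, consecutive arrays as a block or averaged, and leaving out each array. Signal over background and the number of arrays limit the precision.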

Results

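Orb RNA immunoprecipitates from Drosophila ovaries were compared with mock immunoprecipitates on 6 arrays of 1 group, to ask which array spots carried more RNA from the Orb IP than from the mock IP. The median local background volume ranged from 3.04 to 9.19 in the Orb IP channel and from 4.05 to 51.3 in the mock IP channel.

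Signal was concentrated in the Orb IP channel. Between 914 and 1712 spots per array were above background there (5.90% to 11.0% of the 15504 spots outside the control positions), against 140 to 421 in the mock IP channel (0.903% to 2.72%). The order held in both labelling orientations. With Orb IP in Cy3 its channel had 1480 to 1712 such spots and the mock IP 140 to 217. With Orb IP in Cy5 the numbers were 914 to 1412 and 329 to 421. Noise alone can also lift spots past the detection limit, and the number of such spots was not estimated. Counts on single arrays are therefore not counts of spots with RNA. This matters most in the mock IP channel, where the counts are lowest.

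**Figure D1:**
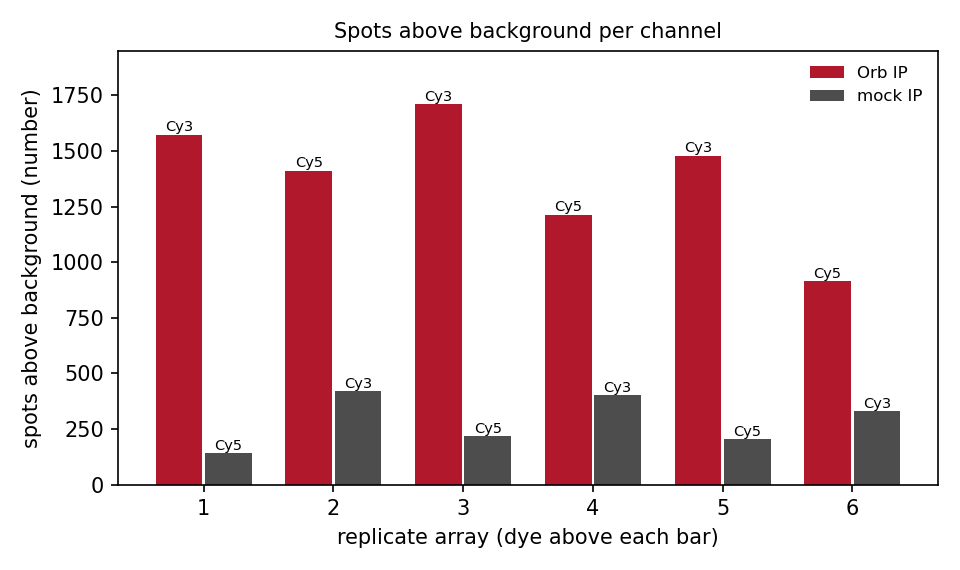
Number of spots above background (vertical axis) in the Orb IP and mock IP channels of each replicate array (horizontal axis), with the dye of each channel above its bar. The Orb IP bars lie between 914 and 1712 and the mock IP bars between 140 and 421.

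On all 6 arrays, 639 spots were above background in the Orb IP channel and 6 in the mock IP channel. All 6 of the latter were also among the 639. Row 1, column 14 of blocks 14 and 22 were among these 6. They lie in the row of the control positions, and whether they are controls is not known. Of the 639, 409 were above background in the mock IP on no array. The 639 include 48 spots in 6 blocks, in runs of 8 consecutive positions of like Orb IP volume in rows 17 and 18. One probe printed 8 times is a candidate explanation of such a run, so the 639 spots may not all be separate probes. The mock IP number depended on replicate 1, whose mock IP channel had the highest background, and was 56 without it. With a limit at 5 SD, the numbers were 364 and 2. Log2 Orb IP volumes of the 639 spots correlated between arrays with Pearson's r of 0.936 to 0.989 and Spearman's rho of 0.883 to 0.983. These correlations are across spots, which are not independent replicates. The 10 brightest of these spots held 17.9% to 26.0% of their summed Orb IP volume on each array.

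For the 639 spots, the lower bound on the ratio of Orb IP to mock IP had a median of 5.40-fold over the 6 arrays. It differed between orientations, as did the mock IP detection limit, which was 2.27 to 13.8 in Cy5 and 0.319 to 0.835 in Cy3. The limits in Cy3 were under 2 robust SDs (SDs of 0.315 to 1.22), since the median of volume minus background was below 0 there. Bounds with Orb IP in Cy5, and averages that include them, can therefore be higher than a true lower bound. The median log2 bound was 0.416 with Orb IP in Cy3 and 4.46 with Orb IP in Cy5, and single arrays ranged from -1.11 on replicate 1 to 5.15 on replicate 4. The mean bound was at least 2-fold at 559 spots, at least 10-fold at 209 and at least 20-fold at 122. It was at least 2-fold on each of the 6 arrays at 125 spots. These bounds were averaged over arrays on the log2 scale. With the ratio of arithmetic means instead, the median was 2.50-fold, and 366, 129 and 81 spots reached 2-fold, 10-fold and 20-fold. Without replicate 1, the median bound was 8.74-fold and 629 spots reached 2-fold.

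**Figure D2:**
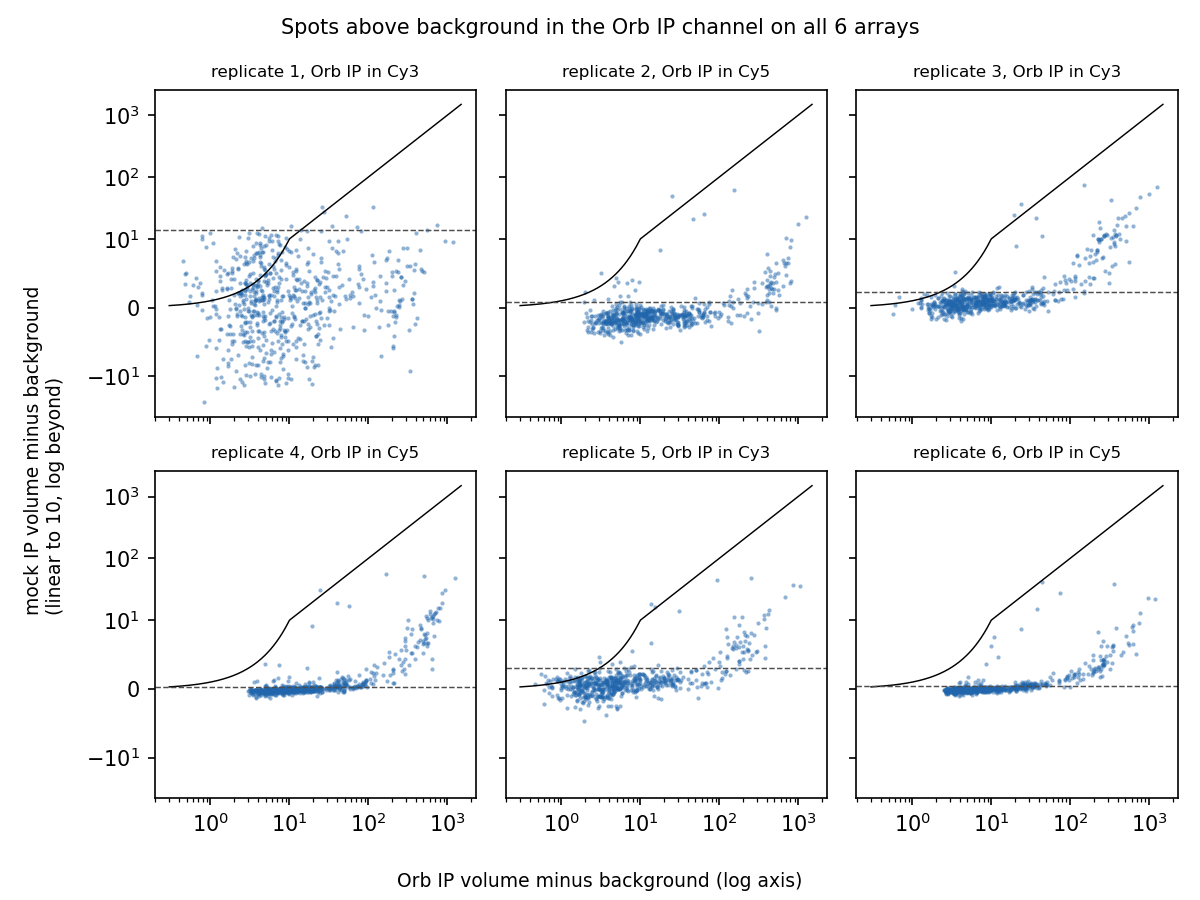
Mock IP volume minus background (vertical axis, linear to 10 and logarithmic beyond) against Orb IP volume minus background (logarithmic horizontal axis) for the 639 spots above background in the Orb IP channel on all 6 arrays, 1 panel per array. The solid line marks equal volumes and the dashed line the mock IP detection limit, which was 13.8 on replicate 1.

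After median centring, limma called 774 of 1432 tested spots higher in the Orb IP and 2 lower, and 93 of the former were at least 2-fold higher. The latter count moved with the background correction, to 226 with offset 10 and 464 without correction. Without the runs in rows 17 and 18, 720 of 1365 tested spots were higher and 77 were at least 2-fold higher. The counts of 774 and 93 are therefore counts of spots and may not all be separate probes. Of the 774, 596 were above background in the Orb IP channel on all 6 arrays. The fixed loess fit called 7 spots higher and 4 lower, with 0 at least 2-fold higher and 2 at least 2-fold lower. At an unadjusted p under 0.05, the loess fit had 451 higher and 15 lower. All 7 spots called higher after loess were also higher after median centring, and 3 of the 4 called lower after loess were higher after median centring. The loess counts were unstable: array weights gave 654 higher and 27 lower, and leaving out any of replicates 2 to 6 gave 0 higher. Scaling on the control positions of columns 6 to 8 in place of median centring gave 181 higher and 1 lower. These columns are called near-equal here, although columns 6 and 8 were higher in the Orb IP on 6 of 6 arrays, by 1.33-fold and 1.2-fold on average. The scaling kept 86 of the 93 spots at least 2-fold higher. The 593 lost calls had a median log2 ratio of 0.115 (median SE 0.0253) before and -0.0688 (median SE 0.107) after.

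The highest log2 ratio after median centring was at block 22, row 3, column 6, with 3.88 (SE 0.124, adjusted p = 8.25e-07, higher on 6 of 6 arrays). Its Orb IP volume was 1200 ± 76.1 and its mock IP volume 34.4 ± 21.1 (SD, n = 6). With the detection limit in place of the mock IP volume on replicate 1, where it was below that limit, the lower bound on the ratio of the means was 34.1-fold. The lowest array, replicate 3, gave 18.2-fold. The spot at block 24, row 4, column 27 followed with 3.65 (SE 0.10, adjusted p = 3.46e-07, higher on 6 of 6 arrays), volumes of 951 ± 54.9 and 28.5 ± 15.4 (SD, n = 6), and a lower bound of 32.6-fold with the same replacement on replicate 1, with 19.0-fold on replicate 3. Both had the volume-to-background ratio of the brightest control positions on all 6 arrays, so their Orb IP volumes were near saturation, and neither their log2 values nor their order is a measured level. Under loess both log2 ratios were negative, at -0.76 (adjusted p = 0.0879) and -0.63 (adjusted p = 0.0214).

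After median centring 2 spots were called lower, with log2 ratios that the offset of 50 brings close to 0 for dim spots. At block 7, row 4, column 5 the log2 ratio was -0.15 (SE 0.0541, adjusted p = 0.0494, lower on 5 of 6 arrays), with an Orb IP volume of 26.1 ± 9.79 and a mock IP volume of 34.9 ± 10.5 (SD, n = 6). This call was lost without any of replicates 1 to 5, and without background correction the log2 ratio was 0.40. It was -1.28 under loess, -0.43 with plain subtraction, where the call was lost (adjusted p = 0.543), and -4.06 with the deposited ratio. The call was also lost with scale normalization, without a filter, with control positions kept, in either orientation alone and with consecutive arrays as a block or averaged. At block 23, row 1, column 1 the log2 ratio was -0.11 (SE 0.0252, adjusted p = 0.0114, lower on 6 of 6 arrays), with volumes of 2.58 ± 1.37 and 6.64 ± 2.91 (SD, n = 6). This spot was above background on 4 arrays in the Orb IP and 5 in the mock IP, so its ratio is not a measured level. It lies in row 1, the row of the control positions, and whether it is a control is not known. The call was lost under loess (adjusted p = 0.134), with near-equal scaling (adjusted p = 0.0508) and with Orb IP in Cy3 only (adjusted p = 0.23). Both channels of the former spot were above background on all 6 arrays.

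At the control positions of columns 3 to 5, volumes of the 2 dyes differed by a median of 0.174%, at volumes near saturation. Column 10 was higher in the Orb IP on 6 of 6 arrays, with a mean log2 ratio before normalization of 1.41 ± 0.363 (SD, n = 6), and so was column 12. Column 9 was lower on 6 of 6 arrays, at -1.34 ± 0.304 (SD, n = 6), and so was column 11. The brighter channel of columns 11 and 12 was near saturation, so no ratio is given. These directions followed the labelled IP and not the dye.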

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

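The tests of loess, of dye bias, of a smear in blocks 18 and 20, of a brighter Orb IP channel and of a repeated probe were chosen after the result was seen, and so was the selection of bright spots. Of 25 series of 6 arrays examined for a lone distant array, 7 had one, where chance gives about 1 in 20 for each series. The series share the same arrays and are not independent, and most of the 7 had replicate 1 as the distant array.

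Replicate 1 stood apart in its mock IP channel, with a median background volume of 51.3 against 4.05 to 14.2 on the others and a noise SD of 6.33 against 0.315 to 1.37. It also stood apart at control positions in the log2 ratio of Orb IP to mock IP: 0.0485 in column 3, 0.045 in column 5, 1.11 in column 6 (0.11 to 0.38 on the others) and 2.14 in column 10 (1.14 to 1.35 on the others). Replicate 6 stood apart in column 4, at 0.174. No biological explanation of these was tested.

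Far fewer spots passed after loess than after median centring. A candidate explanation is that loess fitted the Orb IP signal itself: control positions of column 8, with near-equal volumes, no weight in the curve and intensities within the range of tested spots, went from a mean log2 ratio of 0.116 to -1.47 ± 0.483 (SD, n = 6). Intensity-dependent dye bias as the whole cause is argued against, since each orientation fitted alone after median centring gave more higher than lower calls (335 and 0 with Orb IP in Cy3, 655 and 1 in Cy5), although a first criterion, a median log2 lower bound above 1 in both, was not met (0.416 and 4.46). Of the spots at least 2-fold higher, a share of 0.925 stayed so after scaling on near-equal control positions (median log2 2.43 before and 2.24 after). Those positions were chosen for near-equal volumes in these data, so the scaling could move ratios of 2-fold or more only little. The scaling therefore cannot decide on a brighter Orb IP channel, and that explanation stays open. Near-equal control positions shifted by 0.102 of the median log2 lower bound, or 0.398 with the shift 1 SD higher and arithmetic means. The 593 higher calls lost under that scaling had small ratios, which it moved past 0, from a median log2 of 0.115 (median SE 0.0253) to -0.0688 (median SE 0.107). The scaling shifted dim and bright spots by the same log2 amount, although the offset brings log2 ratios of dim spots close to 0. These values therefore do not decide on a brighter channel either. Enrichment by the Orb antibody is the biological explanation the design gives, and it stays open.

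Over 72 bright spots, mock IP volume rose with Orb IP volume on the arrays other than replicate 1, where Spearman's rho was -0.0762. After each array's trend was removed, the remainders recurred between labelling orientations with rho 0.499 across spots (95% bootstrap interval 0.312 to 0.657, permutation p = 1e-04, the smallest these permutations can give). Across 48 selections of spots and trends, rho ranged from 0.329 to 0.746. This argues against one fixed share of Orb IP signal leaking into the other channel as the whole source, and low amounts of spot-specific RNA in the mock IP may contribute.

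In 6 blocks, 8 positions that follow one another in order, from the end of row 17 to the start of row 18, had Orb IP volumes of like level. In blocks 18 and 20 the next 8 positions were also above background on all 6 arrays, at mean volumes of 9.29 and 10.8 against 39.2 and 42.6. A smear is argued against in the other 4 blocks, where a share of 0.025 of the neighbouring spots was above background on all 6 arrays. In blocks 18 and 20 the share was 0.25. There the neighbouring spots include the first of the next 8 positions, so the share cannot decide on a smear, which stays open. The SD of log2 Orb IP volume within those next 8 positions was 0.2 in block 18 and 0.166 in block 20. The SD of log2 volume within the 8 positions was 0.205 of that between bright spots, and one probe printed 8 times is a candidate explanation. No biological explanation was tested.

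Other assignments of the channels of each array were counted, 32 in all with the real one. After median centring 1 of 32 gave as many calls, with 776 against 0 for the highest other. This count does not exclude chance, since 1 of 32 is the smallest share it can give. It also restates that the signal was one-sided: 759 tested spots were positive on every array, so reversing some arrays sets their values against one another. After loess 2 of 32 gave as many, with 11 calls against 385 for the highest other, so chance is not excluded. With the dye term, the assignment with 385 calls sets replicate 1 against the other arrays. The cause of these calls was not tested.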

How the results depend on the processing

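Median centring as a reported result, the detection limits, the control positions kept, the near-equal scaling, the deposited ratio, the averages of lower bounds and all alternatives of the median-centred and detection counts were chosen after seeing the data. Causes were not tested unless given. Gene list alternatives were not run, since spots have no names, and the planned loess alternatives of named genes were not run for the same reason.

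For the loess counts of 7 higher, 4 lower, 0 at least 2-fold higher and 2 at least 2-fold lower, median centring gave 774, 2, 93 and 0. Print-tip loess gave 0 higher, 0 lower and 0 at least 2-fold lower. Scale normalization gave 252 and 8, and no background correction gave 149, 20, 79 and 7. Plain subtraction, with 281 spots tested, gave 2 higher, 2 at least 2-fold higher and 6 at least 2-fold lower. Offset 10 gave 4, 7 and, at least 2-fold lower, 7. Requiring both channels left 6 spots tested, with 0 higher, 5 lower and 2 at least 2-fold lower. Only Orb IP in Cy3 gave 0 higher, 0 lower and 0 at least 2-fold lower, and only Orb IP in Cy5 gave 0 higher and 1 at least 2-fold lower. Array weights gave 654 and 27. Consecutive arrays as a random block gave 3 higher, and averaged they gave 0, 2 and 1 at least 2-fold lower. Trend and robust options gave 1 at least 2-fold lower. A 5 SD limit gave 4 higher, and keeping the control positions gave 48, 248 and 242 at least 2-fold lower. Leaving out 1 array gave 0 to 20 higher, 0 to 13 lower and 0 to 3 at least 2-fold lower, with 20, 13 and 3 without replicate 1.

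For the median-centred counts of 774 higher, 2 lower, 93 and 0, no background correction gave 1311, 1 and 464. Plain subtraction gave 226 higher, 226 at least 2-fold higher and 3 at least 2-fold lower. Offset 10 gave 226 at least 2-fold higher. Requiring both channels gave 5, 1 and 2. Only Orb IP in Cy3 gave 335 and 0. The lower count was 1 with scale normalization, no filter, only Orb IP in Cy5, and consecutive arrays as a random block or averaged. Should consecutive arrays share RNA, which is not known, the higher count was 688 with them as a random block and 562 averaged. Keeping the control positions gave 49 lower, 140 and 48. Leaving out the runs in rows 17 and 18, with 1365 spots tested, gave 720 higher, 2 lower and 77 at least 2-fold higher. Near-equal scaling gave 181 and 1, with 86 at least 2-fold higher. The deposited ratio, with 281 spots tested, gave 122 higher, all 122 at least 2-fold, and 14 lower, 14 at least 2-fold. Leaving out 1 array gave 569 to 824 higher, with 568 to 722 shared with the 774, and 1 to 2 lower.

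The log2 ratio reversed under loess at block 22, row 3, column 6 (-0.76) and block 24, row 4, column 27 (-0.63), and without background correction at block 7, row 4, column 5 (0.40). The Orb IP detection count of 639 was 364 at 5 SD and 1150 with Orb IP in Cy3 only, and 643 to 839 without 1 array. The mock IP count of 6 was 3 at 3 SD, 2 at 5 SD, 95 with Orb IP in Cy5 only, and 6 to 56 without 1 array, with 56 without replicate 1. Lower bounds of at least 2-fold, 10-fold and 20-fold, at 559, 209 and 122 spots, were reached at 366, 129 and 81 with the ratio of arithmetic means over arrays, and at 629, 285 and 182 without replicate 1. Whether consecutive arrays pair was not settled. Residual correlations were 0.526, 0.211 and 0.0663 for consecutive arrays, and -0.476 to 0.444 for the other pairs of opposite orientation. Mock IP signal near background limits most ratios.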

Other observations

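At 1 spot of block 23, chosen after its values were seen, Orb IP volumes were 43.8, 49.8, 327, 508, 254 and 360 on replicates 1 to 6, and mock IP volumes were -3.14, 1.35, 42.6, 52.7, 47.6 and 38.9.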
